A study of Faecalibacterium prausnitzii with 8 samples.

How the data were processed

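The series holds RNA sequencing of wild-type *Faecalibacterium prausnitzii* strain A2-165 grown in YCFA medium at 37 °C with 0.5% (w/v) galactose, glucose, N-acetylglucosamine (NAG) or fructose, 2 libraries per sugar. Per the labels' protocols, an overnight culture was diluted and grown to an OD600 of 0.4 (glucose, galactose) or 0.2 (fructose, NAG), and cells were fixed in methanol and extracted with phenol and chloroform. Ribosomal RNA was depleted with an NEBNext Bacteria kit, libraries were made with an NEBNext Ultra II RNA kit, which does not mark the strand, and sequencing was paired-end at 76 bases on a NextSeq 500. Per the submitters' processing notes, the tools were Trimmomatic 0.36, HISAT2, featureCounts and DESeq2; the versions of the last 3 and the genome build are not given in the sources used here.

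The deposited data are 6 tables, 1 per pair of sugars, each with the same 2935 genes. The deposited signal values are gene counts that the authors divided by 1 size factor per library, set over all 8 libraries together. This was tested on the tables: in each library 100% of the values were whole multiples of the smallest nonzero value, within 0.001 read; each library had the same values in every table that holds it (largest difference 0), the fructose libraries being given only in the tables against glucose; and the deposited mean of a gene was the mean of all 8 libraries within 4.9e-10. The deposited log2 fold changes are those of the authors, as the second sugar of the table over the first, and the deposited p-values and adjusted p-values are those of the authors' DESeq2 test. Multiplying out the size factors gave whole read counts, on which DESeq2 was run again here; its log2 fold changes lay within 5.1e-10 of the deposited ones in all 6 tables. Every per-library column of the tables was used.

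Product names in the tables gave each gene its annotation, and 577 of the 2935 genes are annotated as hypothetical proteins. Gene levels in the text are deposited normalized counts, given as mean ± SD of 2 libraries. Counts per unit of depth were taken over the recovered reads, and 3 reads served as the floor.

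The choices of test, filter, threshold, gene lists and named genes were made before the data were examined, with the exceptions given here. The plan was an edgeR quasi-likelihood test if the tables held raw counts, in 1 fit of all 8 libraries if the tables gave a library the same counts, and otherwise limma-trend on log2(value + 1) within each table. As the values were normalized but identical in the tables that share a library and scaled together, limma-trend was run once on all 8 libraries with 1 mean per sugar; this departs from the plan, and the fit of only the 4 libraries compared was run as an alternative. Genes with a mean normalized count of at least 1 were tested (2727 of 2935), with a pseudocount of 1, 4 residual and 8.51 prior degrees of freedom, and a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Comparisons were the 6 pairs of sugars; genes specific to 1 sugar (past the test and at least 2-fold in the same direction against each of the other 3); and genes separating fructose and NAG from glucose and galactose (past the test in the same direction in all 4 cross comparisons). With edgeR and TMM factors on the recovered reads, 1168 genes passed in fructose minus glucose, 945 in NAG minus glucose, 38 in galactose minus glucose, 1194 in fructose minus galactose, 1014 in NAG minus galactose and 650 in fructose minus NAG. DESeq2 without independent filtering, which gave an adjusted p to 2902 genes, called 933, 769, 43, 964, 818 and 451 in the same order.

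Gene lists were 25 groups matched by words in the product names. Of these, 24 were tested with camera, at a correlation of 0.01 between genes and with at least 5 genes each; the list for ribosomal and transfer RNA genes matched only enzymes that modify these RNAs and was left out. The tested lists are PTS components, fructose use, N-acetylglucosamine and amino sugar use, galactose use, glycolysis, pyruvate and butyrate fermentation, pentose phosphate and pentose use, sugar ABC transporters, glycoside hydrolases and glycogen, sugar-type transcription regulators, ribosomal proteins and aminoacyl-tRNA synthetases. The others are ATP synthase, amino acid biosynthesis, nucleotide biosynthesis, chaperones and proteases, redox and oxygen defence, cell wall synthesis, cell division and DNA replication, sporulation-type genes, phage and mobile elements, B vitamin and cofactor synthesis, iron and metal transport, and phosphate and peptide transport. Matching by words also brought in 4 6-phosphofructokinases under fructose use, PTS sugar subunits under sugar ABC transporters, a tRNA-modifying enzyme under ATP synthase, iron-sulfur enzymes under iron transport and pyruvate:ferredoxin oxidoreductase under redox. Adjusted p-values were also computed over each list alone.

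Named genes follow a fixed rule per comparison: the 8 largest rises and 8 largest falls among genes past the test whose libraries did not overlap and whose mean was at least 10 CPM in the higher group; every tested gene of the PTS, fructose, amino sugar and galactose lists; and the 3 largest changes past the test in each other list with a call. For genes specific to a sugar, up to 8 were taken by the smallest of their 3 absolute fold changes. These had a mean of at least 10 CPM on at least 1 sugar. The text names part of these, from the top.

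Alternatives were edgeR with RLE or upper quartile factors, DESeq2, no low-value filter, only the 4 libraries compared, a block for the replicate number, pseudocounts of 0.1 and 5, an adjusted p under 0.01, a 2-fold limit, each of the 8 libraries left out in turn, camera with an estimated correlation, and fry. Added after the data were seen were edgeR with TMM factors and total-count scaling. Simulated data with no effect (20 draws) gave a mean of 0.433 calls per comparison, and 4.2% of lists had an unadjusted camera p under 0.05. The simulated genes were drawn independently of each other, so this share cannot check the correlation set for camera. In simulated fructose minus glucose data with 200 changed genes (5 draws), limma-trend recovered 43.9% of those changed 1.5-fold, 84.8% at 2-fold and 98.5% at 4-fold, and 5.03% of its calls were false. The changed genes had a mean of at least 20, as many were raised as lowered, and only fructose was changed. The recovery rates do not cover genes of lower level, and no rate here covers data with more changed genes. With an estimated correlation between genes, camera called 0 of the 24 lists in each of the 6 comparisons, while 2, 1, 3, 3, 1 and 2 lists had an unadjusted p under 0.05 and fry called 14, 17, 1, 15, 17 and 5 (same order as above). The camera test compares a list with the other genes, while fry asks whether the list itself shifted up or down as a whole. The 2 thus answer different questions. Fry results are from this directional test unless called mixed, and the mixed test takes changes in either direction. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Antisense transcription was not analysed here.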

Results

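RNA was sequenced from *Faecalibacterium prausnitzii* A2-165, a butyrate-producing anaerobe of the human gut, grown in YCFA medium with galactose, glucose, N-acetylglucosamine (NAG) or fructose as the added sugar. Each sugar had 2 libraries, 8 in all. Per the labels' protocols, cultures on glucose and galactose were harvested at an optical density (OD600) of 0.4 and those on fructose and NAG at 0.2. Counted reads came to 2245053 and 2816706 on galactose, 1603318 and 2112575 on glucose, 3143800 and 1332716 on NAG, and 2142082 and 1521239 on fructose. Of the 2935 genes, 2673 to 2799 had a read in a given library, and the 10 most abundant genes took 20.6% to 23.9% of its reads. A floor of 3 reads was worth 0.954 to 2.25 CPM (reads scaled to the size of the library), which covers counting error only. The 2 libraries of a sugar correlated across genes with r = 0.988 on galactose, 0.984 on glucose, 0.986 on NAG and 0.981 on fructose (genes are not independent replicates). They differed by more than counting noise in all 4 sugars (chi-square per degree of freedom 7.15, 4.82, 11.8 and 17.7). No label says that the 2 libraries of a sugar came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Levels below are normalized counts, as mean ± SD with n = 2, and fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. Genes taken as the largest rises and falls of a pair had both libraries of the one sugar above both of the other in CPM. This was not required of genes named from the lists or of the counts of rises and falls, which rest on the test alone.

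The series title concerns the function of the phosphotransferase system (PTS), which takes up sugars and phosphorylates them on entry, so each comparison asks which genes differed between a pair of sugars, PTS genes among them. The first principal component held 56.4% of the variance and set galactose and glucose apart from fructose and NAG. The second held 15.9% and set NAG apart from fructose.

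**Figure D1:**
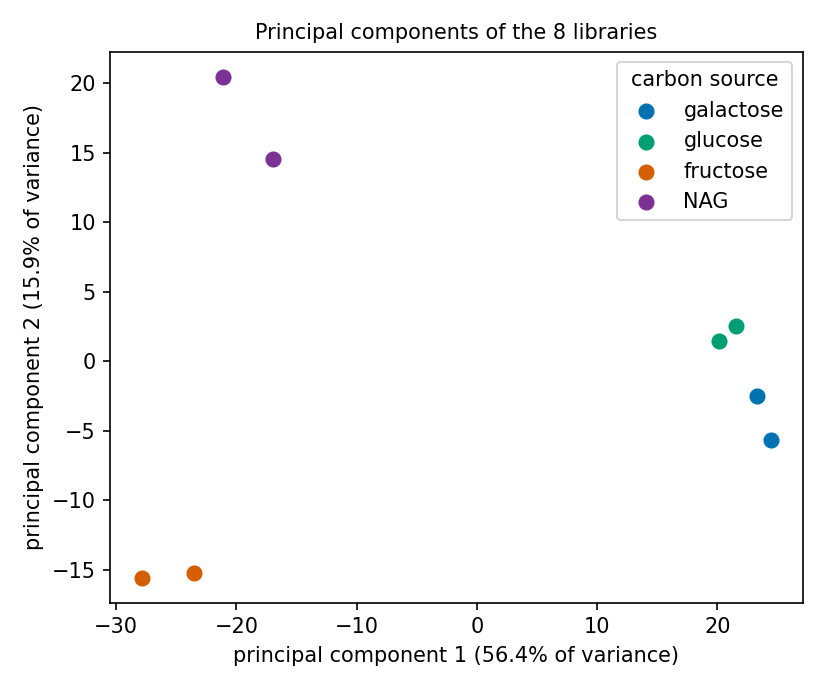
Principal components of log2(normalized count + 1) over the 2727 genes tested, 1 point per library, coloured by sugar (2 libraries each); the axes are component scores, with their share of the variance. On the first component galactose and glucose sit between 20.2 and 24.5 and fructose and NAG between -27.9 and -17.0; on the second NAG sits at 14.5 and 20.5 and fructose at -15.5 and -15.2.

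Between galactose and glucose, harvested at the same density, genes for the breakdown of galactose rose on galactose. The galactokinase gene GXM22_RS09950, for the enzyme that phosphorylates galactose, stood at 3952 ± 5.31 on galactose and 1144 ± 40.9 on glucose (log2 fold change 1.79, SE 0.11, limma-trend adjusted p = 2.0e-06). Its neighbour in the numbering, the hexose-1-phosphate uridylyltransferase gene GXM22_RS09955, stood at 5982 ± 49.4 and 1708 ± 119 (log2 fold change 1.81, SE 0.13, limma-trend adjusted p = 2.5e-06). In the galactose use list 3 of 8 rose and 0 fell (3 and 0 adjusted over the list alone). The list as a whole was higher (camera adjusted p = 2.8e-06, and adjusted p = 0.13 with an estimated correlation). A further galactokinase-annotated gene, GXM22_RS08590, was at 154 ± 16.1 and 120.3 ± 3.99 and did not pass (limma-trend adjusted p = 0.55).

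Other genes rose on galactose as well. GXM22_RS09875, for the binding protein of an amino acid ABC transporter, stood at 537 ± 54.3 on galactose and 22.5 ± 8.62 on glucose (log2 fold change 4.56, SE 0.34, limma-trend adjusted p = 4.1e-06). Cysteine synthase A (GXM22_RS02915), which makes cysteine from O-acetylserine and sulfide, stood at 16897 ± 8653 and 701 ± 224 (log2 fold change 4.52, SE 0.30, limma-trend adjusted p = 2.1e-06). GXM22_RS09880, annotated only as an ABC transporter permease subunit, stood at 1683 ± 278 and 90.04 ± 51.9 (log2 fold change 4.33, SE 0.34, limma-trend adjusted p = 8.1e-06). GXM22_RS13780, for an O-acetylhomoserine sulfhydrylase-type enzyme, stood at 17602 ± 772 and 5033 ± 820.4 (log2 fold change 1.82, SE 0.16, limma-trend adjusted p = 2.9e-05). A second gene with the same product name, GXM22_RS12840, was at 155 ± 13.4 and 145 ± 13.2 and did not pass (limma-trend adjusted p = 0.92). Near GXM22_RS09875 in the numbering, the toxin gene GXM22_RS09865 and the antitoxin gene GXM22_RS09870 rose too, with log2 fold changes of 2.17 and 2.11. In the amino acid synthesis list 2 of 49 genes passed, both named above (the same number adjusted over the list alone). The list was higher (camera adjusted p = 0.034, and adjusted p = 0.93 with an estimated correlation). That call was lost without galactose replicate 2, glucose replicate 1 or glucose replicate 2. Fry asks whether the list itself shifted up or down as a whole, not how it compares with other genes. By fry the list did not pass (adjusted p = 0.34). By the mixed fry test, which takes changes in either direction, it passed (adjusted p = 7.2e-04).

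Among PTS genes, 1 of the genes for each shared phosphate carrier fell on galactose. GXM22_RS01245, for the carrier HPr, stood at 276 ± 12.2 on galactose and 583 ± 50.1 on glucose (log2 fold change -1.08, SE 0.15, limma-trend adjusted p = 0.0015). GXM22_RS01250, for enzyme I, which passes phosphate from phosphoenolpyruvate to HPr, stood at 616 ± 0.973 and 1238 ± 50.4 (log2 fold change -1.01, SE 0.12, limma-trend adjusted p = 4.9e-04). A second HPr gene, GXM22_RS11900 (1557 ± 166 and 1400.4 ± 102, limma-trend adjusted p = 0.81), and a second enzyme I gene, GXM22_RS00575 (325 ± 1.56 and 291 ± 61.2, limma-trend adjusted p = 0.79), did not pass. A membrane EIIC gene that was abundant on both sugars, GXM22_RS00590, rose to 24676 ± 394 from 15336 ± 317 (log2 fold change 0.69, SE 0.12, limma-trend adjusted p = 0.0081). That call was lost without galactose replicate 1 (limma-trend adjusted p = 0.087), galactose replicate 2 (0.14), glucose replicate 1 (0.12) and glucose replicate 2 (0.051). The other 16 of 19 PTS genes did not pass (1 rose and 2 fell adjusted over the list alone). The largest fall was that of GXM22_RS09290, for a class III fructose-bisphosphatase, an enzyme of gluconeogenesis, at 50.9 ± 1.48 against 130.1 ± 13.4 (log2 fold change -1.33, SE 0.20, limma-trend adjusted p = 0.0029).

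Other lists had few genes past the test between galactose and glucose. In the sugar ABC transporter list 2 of 27 rose and 1 fell (3 and 3 adjusted over the list alone), led by the permease gene GXM22_RS08050 (log2 fold change 1.25). Its call was lost without galactose replicate 2 (limma-trend adjusted p = 0.16) and glucose replicate 1 (0.053), with DESeq2 (adjusted p = 0.06) and in a fit of only the 4 libraries compared (adjusted p = 0.059). The glycoside hydrolase and glycogen list was lower (camera adjusted p = 3.2e-04, and adjusted p = 0.25 with an estimated correlation). By fry, which asks whether the list itself shifted up or down as a whole, it did not pass (adjusted p = 0.18). By the mixed fry test it passed (adjusted p = 7.2e-04). Of its 21 genes 1 passed, and 5 adjusted over the list alone. That gene, the family 2 glycoside hydrolase GXM22_RS13685 (log2 fold change -0.87), lost its call without galactose replicate 1 (limma-trend adjusted p = 0.092), galactose replicate 2 (0.18) and glucose replicate 1 (0.13). The ATP synthase list was lower (camera adjusted p = 1.3e-04, and adjusted p = 0.25 with an estimated correlation) but did not pass by fry (adjusted p = 0.18). Of its 16 genes 0 passed by limma-trend, edgeR or DESeq2, and 8 were lower at an unadjusted p under 0.05. Iron transport gene GXM22_RS11200 (FeoB) stood at 2138 ± 160.2 and 946 ± 423 (log2 fold change 1.25, SE 0.27, limma-trend adjusted p = 0.041). It was the 1 of 20 genes of its list to pass, and its call was lost without galactose replicate 1 (limma-trend adjusted p = 0.32), galactose replicate 2 (0.23), glucose replicate 2 (0.19), with DESeq2 (adjusted p = 0.18), with total-count scaling (adjusted p = 0.066), with no low-value filter (adjusted p = 0.056) and at a pseudocount of 0.1 (adjusted p = 0.06). The B vitamin list had 1 rise and 1 fall among 56 genes and the phosphate and peptide transport list 1 rise among 17, that of GXM22_RS09875 (the same counts adjusted over each list alone). The cell division and replication list had 1 rise among 33 (2 adjusted over the list alone), in the topoisomerase gene GXM22_RS06450, at 8.26 ± 1.97 and 0.684 ± 0.968, near the floor. That rise was lost without galactose replicate 1 (limma-trend adjusted p = 0.087), galactose replicate 2 (0.22), glucose replicate 2 (0.063), with edgeR TMM factors (adjusted p = 0.095), with edgeR RLE factors (adjusted p = 0.086), with edgeR upper quartile factors (adjusted p = 0.094), with DESeq2 (adjusted p = 0.42), in a fit of only the 4 libraries compared (adjusted p = 0.092), at a pseudocount of 0.1 (adjusted p = 0.06) and at a pseudocount of 5 (adjusted p = 0.055).

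In 15 lists limma-trend called 0 genes between galactose and glucose, and so did edgeR and DESeq2 except for 1 phage gene lower by DESeq2. At an unadjusted p under 0.05 they held 0 of 6 fructose use genes, 5 of 8 amino sugar genes (4 higher and 1 lower, which also passed adjusted over the list alone), 1 of 15 in glycolysis, 0 of 20 in butyrate fermentation and 0 of 9 in pentose use. Further such counts were 4 of 21 sugar-type regulators and 0 of 56 ribosomal proteins. The rest were 2 of 21 tRNA ligases, 8 of 16 in ATP synthase, 1 of 27 in nucleotide synthesis, 4 of 24 chaperones and proteases (2 higher adjusted over the list alone), 1 of 8 redox genes, 2 of 19 in cell wall synthesis, 3 of 27 of sporulation type and 12 of 102 phage and mobile genes. In all, 42 of 2727 genes passed between galactose and glucose, 26 higher and 16 lower on galactose. Of these, 20 and 3 changed by at least 2-fold. The authors' deposited table has 46 genes (26 higher and 20 lower) at an adjusted p under 0.05. The count was 20 without galactose replicate 1, 20 without galactose replicate 2, 25 without glucose replicate 1 and 65 without fructose replicate 2. With a replicate block it was 98 (55 higher and 43 lower).

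Between fructose and glucose, a run of 3 adjacent gene numbers rose on fructose. GXM22_RS09805, for a PTS EIIA subunit, stood at 2687 ± 167 on fructose and 208 ± 41.9 on glucose (log2 fold change 3.69, SE 0.16, limma-trend adjusted p = 1.2e-08). GXM22_RS09800, for 1-phosphofructokinase, which phosphorylates the fructose 1-phosphate that a fructose PTS makes, stood at 686 ± 42.3 and 55.6 ± 0.654 (log2 fold change 3.6, SE 0.23, limma-trend adjusted p = 1.9e-07). GXM22_RS09795, for a DeoR-type regulator, stood at 539.9 ± 16.7 and 45.6 ± 11 (log2 fold change 3.56, SE 0.25, limma-trend adjusted p = 4.4e-07). In the PTS list 3 of 19 rose and 2 fell (3 and 2 adjusted over the list alone). Enzyme I (GXM22_RS01250, log2 fold change 1.06) and HPr (GXM22_RS01245, 0.82) were the other rises. The EIIC gene GXM22_RS00590 stood at 1651 ± 70.4 against 15336 ± 317 (log2 fold change -3.22, SE 0.12, limma-trend adjusted p = 4.0e-09). The HPr kinase gene GXM22_RS07750 had a log2 fold change of -0.75, lost without fructose replicate 2 (limma-trend adjusted p = 0.089) and glucose replicate 1 (0.056) and with total-count scaling (adjusted p = 0.089). The gene annotated as a glucose IIA subunit, GXM22_RS01420, did not pass (445 ± 14.6 and 444 ± 14.9, limma-trend adjusted p = 0.99).

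In the fructose use list 2 of 6 rose and 3 fell (2 and 3 adjusted over the list alone). Besides GXM22_RS09800 that list had matched 4 6-phosphofructokinase genes of glycolysis and a putative fructokinase (GXM22_RS12935, 58.6 ± 9.44 and 53.9 ± 10.5, limma-trend adjusted p = 0.85). The 6-phosphofructokinase gene GXM22_RS07725 stood at 1201 ± 300.2 against 4567 ± 71.2 (log2 fold change -1.95, SE 0.15, limma-trend adjusted p = 7.6e-07). The galactose use list was lower (camera adjusted p = 0.043, and adjusted p = 0.51 with an estimated correlation), with 3 of 8 genes lower (3 adjusted over the list alone). GXM22_RS09950 fell by 1.97 on the log2 scale (SE 0.11, limma-trend adjusted p = 7.9e-08), with its neighbour GXM22_RS09955 at -1.86. The list's median of -0.20 became 0.08 under total-count scaling. Its camera call was lost without fructose replicate 2 (camera adjusted p = 0.14). In the amino sugar list 5 of 8 rose and 2 fell (5 and 3 adjusted over the list alone), led by N-acetylneuraminate lyase (GXM22_RS08055, log2 fold change 1.93), which splits sialic acid, and N-acetylmannosamine-6-phosphate epimerase (GXM22_RS08065, 1.72).

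The largest rises on fructose included an uncharacterised gene, GXM22_RS00900 (303 ± 30.7 against 2.73 ± 1.92, log2 fold change 6.45, SE 0.38, limma-trend adjusted p = 7.9e-08). The metallo-hydrolase gene GXM22_RS00435 stood at 2356 ± 819 against 96.9 ± 30.6 (log2 fold change 4.58, SE 0.38, limma-trend adjusted p = 1.4e-06). Uncharacterised GXM22_RS14825 stood at 7616 ± 1838 against 334 ± 31.6 (log2 fold change 4.49, SE 0.19, limma-trend adjusted p = 9.8e-09). GXM22_RS00440, a sugar ABC transporter permease gene, followed (1044 ± 419 against 71.3 ± 29.2, log2 fold change 3.85, SE 0.42, limma-trend adjusted p = 1.7e-05). Its partner permease GXM22_RS00445 had a log2 fold change of 3.83. The deepest falls were in ferrous iron uptake. The FeoA gene GXM22_RS11210 stood at 2.26 ± 1.55 against 76.5 ± 44.6 (log2 fold change -4.53, SE 0.45, limma-trend adjusted p = 6.8e-06), with a second FeoA gene, GXM22_RS11205, at -3.93. FeoB (GXM22_RS11200) stood at 45 ± 13.9 against 946 ± 423 (log2 fold change -4.32, SE 0.27, limma-trend adjusted p = 1.5e-07). Also down were GXM22_RS13780 (398 ± 83.8 against 5033 ± 820.4, log2 fold change -3.66, SE 0.16, limma-trend adjusted p = 1.2e-08) and the permease gene GXM22_RS09880 (log2 fold change -3.49).

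Genes of the translation machinery fell together on fructose. Of 56 ribosomal protein genes 51 fell and 1 rose (1 higher and 52 lower adjusted over the list alone). The list was lower (camera adjusted p = 6.3e-18, and adjusted p = 0.62 with an estimated correlation). Examples are L30 (GXM22_RS13375, 979 against 2384, log2 fold change -1.29) and S3 (GXM22_RS13435, -1.28). The exception was an S1-type gene of low level, GXM22_RS07155 (45.4 ± 16.4 against 14.5 ± 6.96), whose call was lost without fructose replicate 1 (limma-trend adjusted p = 0.061) and glucose replicate 1 (0.056). Of 21 tRNA ligase genes 17 fell (0 higher and 18 lower adjusted over the list alone), led by those for tyrosine (GXM22_RS07535, -1.24) and alanine (GXM22_RS04910, -1.06). This list was lower as well (camera adjusted p = 9.3e-07, and adjusted p = 0.62 with an estimated correlation). Genes of ATP synthase rose, 14 of 16 (14 higher and 0 lower adjusted over the list alone), such as the delta (GXM22_RS01125, 0.98) and B subunits (GXM22_RS01120, 0.91). That list, which also holds a tRNA-modifying enzyme by its product name, was higher (camera adjusted p = 3.4e-05, and adjusted p = 0.32 with an estimated correlation). Phage and mobile element genes rose, 44 of 102 with 0 lower (44 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.4e-05, and adjusted p = 0.32 with an estimated correlation). Among them were a major capsid gene (GXM22_RS11130, 56.3 against 4.95) and a phage antirepressor (GXM22_RS01650, 2.90).

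**Figure D2:**
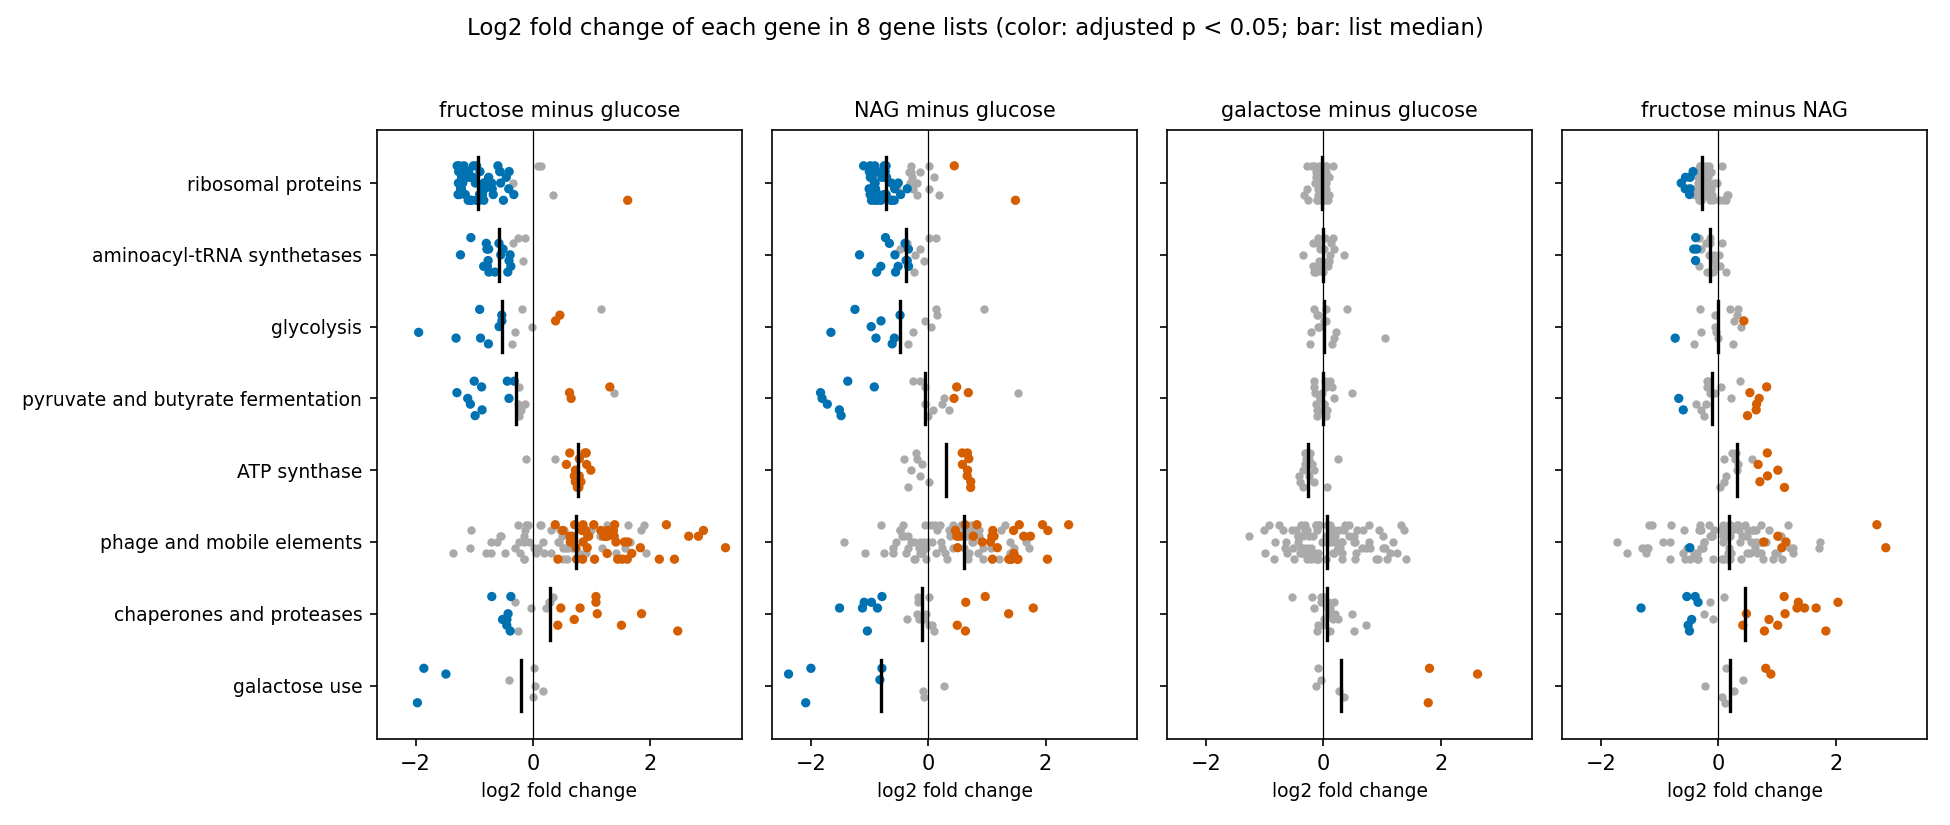
Log2 fold changes (horizontal axis, log2 scale) of the genes of 8 lists (vertical axis) in 4 comparisons, 1 point per gene. Orange and blue mark genes higher and lower at a limma-trend adjusted p under 0.05. Grey marks the others, and the bar is the list median. Ribosomal protein genes lie below 0 in fructose minus glucose (median -0.94) and NAG minus glucose (-0.72) and around 0 in galactose minus glucose (-0.02); the median for galactose use in fructose minus glucose, -0.20, turns to 0.08 under total-count scaling.

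In glycolysis 2 of 15 rose and 8 fell (2 and 9 adjusted over the list alone; camera adjusted p = 0.02, and adjusted p = 0.73 with an estimated correlation), a call lost without fructose replicate 2 (camera adjusted p = 0.13) and without glucose replicate 1 (camera adjusted p = 0.058). After the 6-phosphofructokinases came pyruvate kinase (GXM22_RS10810, log2 fold change -0.91). In the butyrate fermentation list 3 of 20 rose and 10 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.02, and adjusted p = 0.73 with an estimated correlation). Its median of -0.29 became -0.01 under total-count scaling. Phosphate acetyltransferase (GXM22_RS09375), which links acetyl-CoA to acetate, rose to 2245 ± 600.3 from 890.1 ± 37.7 (log2 fold change 1.31, SE 0.16, limma-trend adjusted p = 4.3e-05). By contrast, acetyl-CoA acetyltransferase (GXM22_RS07055), the entry to the butyrate pathway, fell to 9966 ± 1125 from 24475 ± 2459 (log2 fold change -1.30, SE 0.16, limma-trend adjusted p = 4.1e-05). The B vitamin list was lower (2 of 56 rose and 11 fell, 1 and 10 adjusted over the list alone; camera adjusted p = 0.02, and adjusted p = 0.73 with an estimated correlation), led by a folate enzyme gene (GXM22_RS09610, -1.60). The B vitamin median of -0.27 became 0.02 under total-count scaling. The B vitamin call was lost without fructose replicate 1 (camera adjusted p = 0.1) and with edgeR RLE factors (adjusted p = 0.076). Among sugar ABC transporters 11 of 27 rose and 8 fell (12 and 8 adjusted over the list alone). This list also holds PTS subunits named as sugar transporters. Glycogen phosphorylase (GXM22_RS03545) led the glycoside hydrolase and glycogen list (42.3 against 250.5, log2 fold change -2.54), in which 6 of 21 rose and 8 fell (6 and 8 adjusted over the list alone). Among chaperones and proteases 10 of 24 rose and 7 fell (11 and 7 adjusted over the list alone), led by the small heat-shock gene GXM22_RS06055 (2.47) and FtsH protease (GXM22_RS11510, 1.85).

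Rises and falls in the lists not yet named, whose camera calls did not pass between fructose and glucose, were 4 and 11 of 49 amino acid synthesis genes, 7 and 12 of 27 in nucleotide synthesis, 1 and 1 of 9 in pentose use and 6 and 3 of 21 sugar-type regulators. They were 3 and 1 of 8 redox genes, 2 and 9 of 19 in cell wall synthesis, 5 and 9 of 33 in cell division and replication and 4 and 2 of 27 of sporulation type. The last were 2 and 4 of 20 iron and metal genes (median 0.15, mean -0.49) and 1 and 6 of 17 in phosphate and peptide transport. Over all genes, 1165 of 2727 passed, 574 higher and 591 lower on fructose, 329 and 153 by at least 2-fold. For this pair the authors' deposited table has 954 genes (436 higher and 518 lower). Total-count scaling moved the median gene by 0.28 on the log2 scale and the higher share of calls from 49.3% to 73.4%, with no call reversed. The fructose cultures were harvested at OD600 0.2 and the glucose cultures at 0.4, so sugar and density cannot be told apart.

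**Figure D3:**
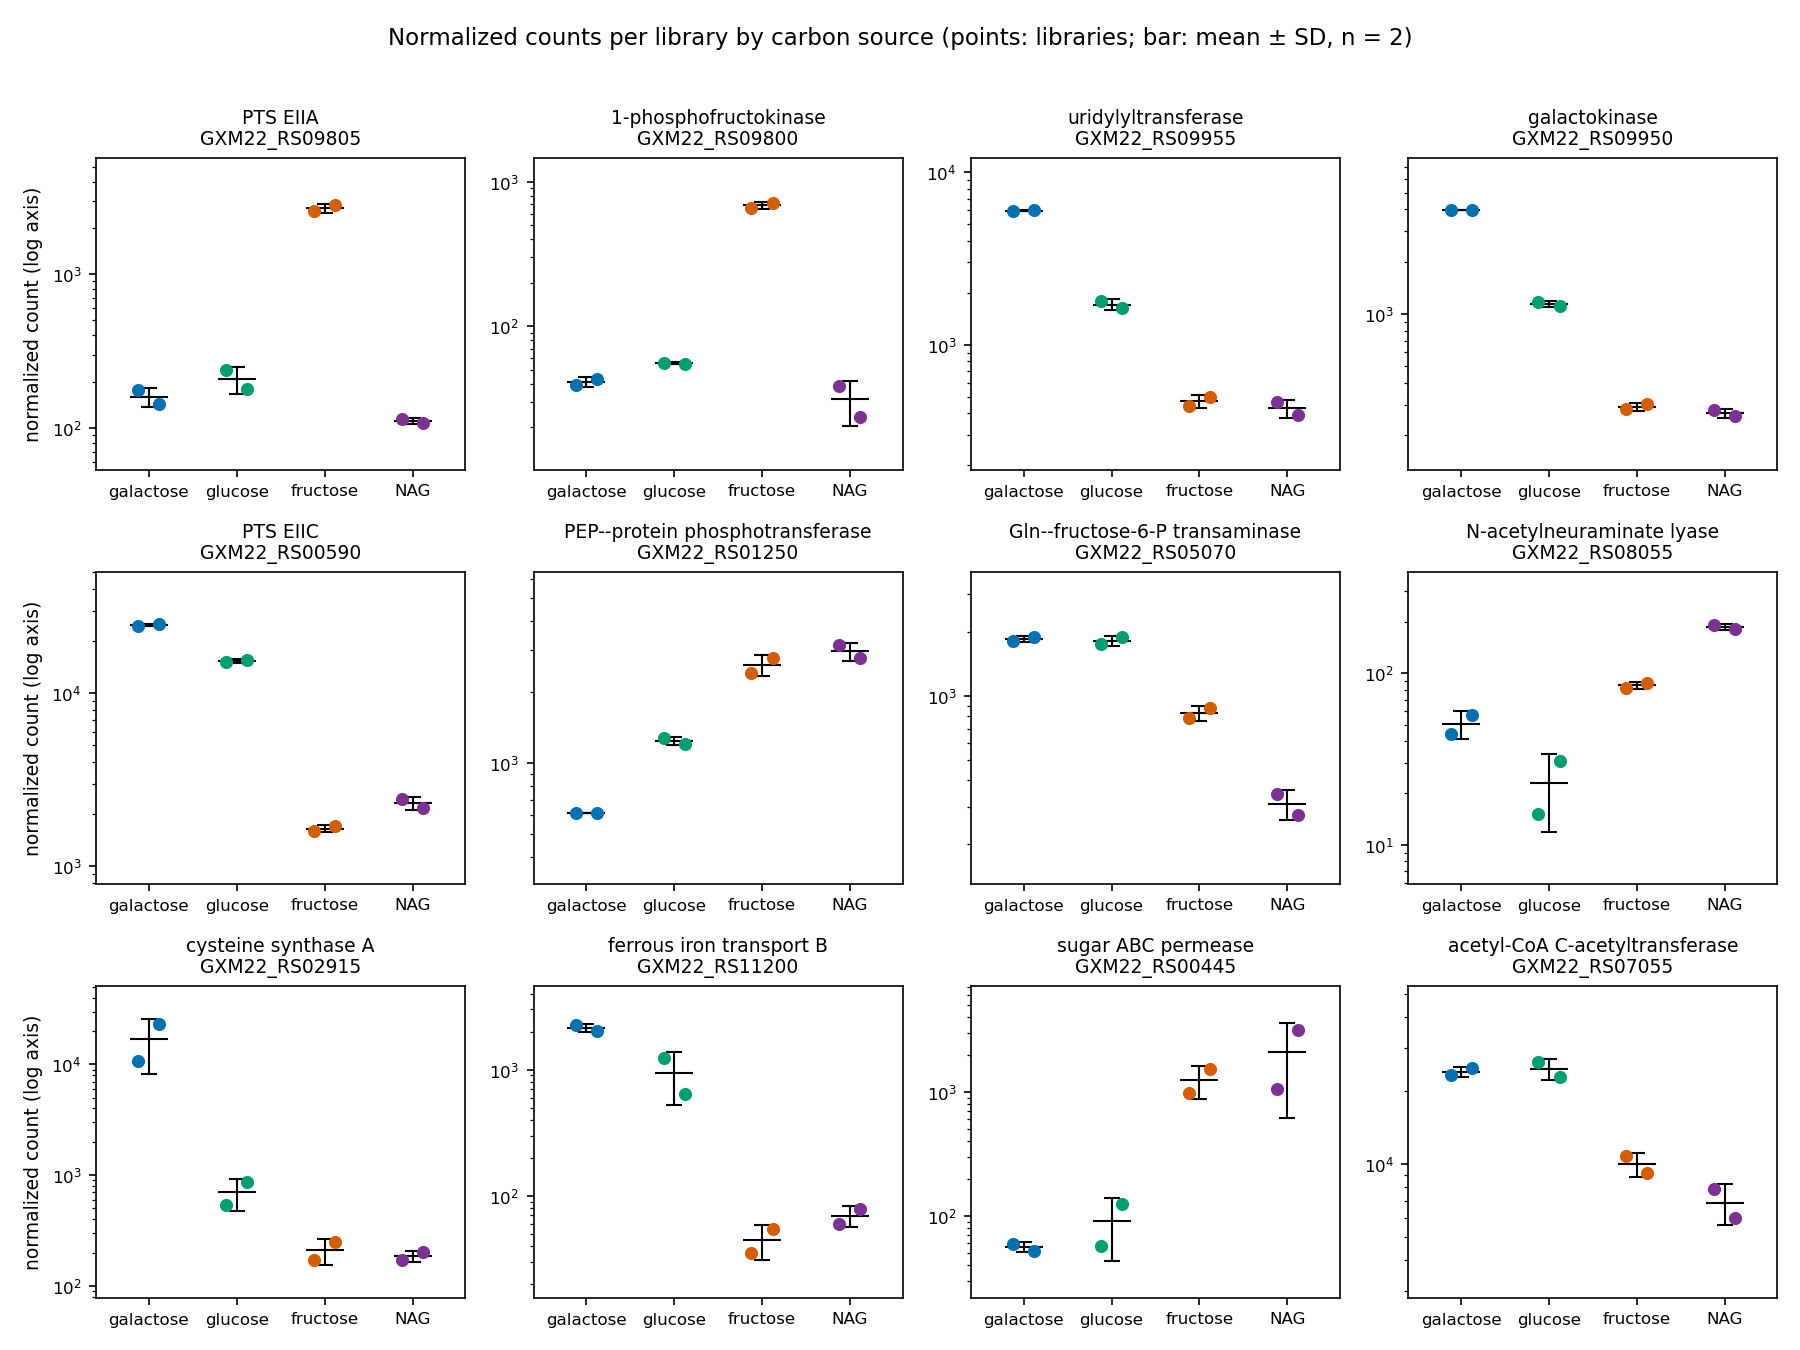
Normalized counts of 12 genes in each library (vertical log axis), by sugar, with mean ± SD of the 2 libraries. GXM22_RS09805 and GXM22_RS09800 stand highest on fructose (2687 and 686), GXM22_RS09955 and GXM22_RS09950 on galactose (5982 and 3952), and GXM22_RS00590 lies at 24676 on galactose, 15336 on glucose, 1651 on fructose and 2323 on NAG.

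Between NAG and glucose, the enzymes that release and deaminate glucosamine 6-phosphate did not pass, while genes for sialic acid use rose. Glucosamine-6-phosphate deaminase (GXM22_RS00595) stood at 1680.3 ± 1.38 on NAG and 1507 ± 107 on glucose (log2 fold change 0.16, SE 0.12, limma-trend adjusted p = 0.34). N-acetylglucosamine-6-phosphate deacetylase (GXM22_RS00600) stood at 2683 ± 137 and 2319 ± 49.8 (log2 fold change 0.21, SE 0.11, limma-trend adjusted p = 0.17). N-acetylneuraminate lyase (GXM22_RS08055) stood at 187 ± 7.71 and 22.9 ± 11 (log2 fold change 3.06, SE 0.29, limma-trend adjusted p = 6.2e-06). N-acetylmannosamine-6-phosphate epimerase (GXM22_RS08065) stood at 57 ± 8.2 and 7.68 ± 0.748 (log2 fold change 2.74, SE 0.32, limma-trend adjusted p = 4.0e-05). In the amino sugar list 3 of 8 rose and 1 fell (3 and 1 adjusted over the list alone). The fall was that of the cell wall enzyme UDP-N-acetylglucosamine diphosphorylase (GXM22_RS01290, -1.30). Glutamine-fructose-6-phosphate transaminase (GlmS, GXM22_RS05070), which makes glucosamine 6-phosphate from fructose 6-phosphate, stood at 311 ± 50.4 against 1816 ± 92.7 (log2 fold change -2.55, SE 0.13, limma-trend adjusted p = 2.5e-08).

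Of the PTS genes 2 of 19 rose and 4 fell (2 higher and 4 lower adjusted over the list alone). Enzyme I (GXM22_RS01250) stood at 2966 ± 252 against 1238 ± 50.4 (log2 fold change 1.26, SE 0.12, limma-trend adjusted p = 6.1e-06). HPr (GXM22_RS01245) stood at 1117 ± 192 against 583 ± 50.1 (log2 fold change 0.93, SE 0.15, limma-trend adjusted p = 3.4e-04). The EIIC gene GXM22_RS00590, whose number stands beside those of GXM22_RS00595 and GXM22_RS00600, was lower on NAG, 2323 ± 197 against 15336 ± 317 (log2 fold change -2.72, SE 0.12, limma-trend adjusted p = 4.4e-09). The EIIA gene GXM22_RS09805 (log2 fold change -0.88) and the HPr kinase gene GXM22_RS07750 (-1.06) also fell. So did GXM22_RS14870 (-0.90), the other gene with the product name EIIC, a call lost without NAG replicate 1, NAG replicate 2 or glucose replicate 1. In the fructose use list 0 of 6 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.039, and adjusted p = 0.4 with an estimated correlation), a call lost without NAG replicate 2 (camera adjusted p = 0.15) and with edgeR RLE factors (adjusted p = 0.082). GXM22_RS07725 fell by 1.66 on the log2 scale (SE 0.15, limma-trend adjusted p = 4.1e-06). In the galactose use list 0 of 8 rose and 5 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.4 with an estimated correlation). Of these, GXM22_RS09950 stood at 269 against 1144 and GXM22_RS09955 at 428 against 1708 (log2 fold changes -2.09 and -2.0).

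The largest rises on NAG included an uncharacterised gene, GXM22_RS09480 (1209 ± 353 against 39.8 ± 0.119, log2 fold change 4.86, SE 0.20, limma-trend adjusted p = 3.7e-09), and genes from a run of neighbouring numbers. In that run were the metallo-hydrolase GXM22_RS00435 (2480.3 ± 1635 against 96.9 ± 30.6, log2 fold change 4.52, SE 0.38, limma-trend adjusted p = 2.4e-06) and the sugar ABC permeases GXM22_RS00445 and GXM22_RS00440 (log2 fold changes 4.40 and 4.31). It also held the binding protein GXM22_RS00460 (5853 ± 4063 against 359 ± 120.1, log2 fold change 3.87, SE 0.38, limma-trend adjusted p = 8.2e-06) and the response regulator GXM22_RS00450 (3.57). Outside the run were the topoisomerase gene GXM22_RS06450 (26.2 ± 5.98 against 0.684 ± 0.968, log2 fold change 4.13, SE 0.49, limma-trend adjusted p = 4.1e-05) and uncharacterised GXM22_RS09730 (2988 ± 89.3 against 250 ± 3.33, log2 fold change 3.57, SE 0.14, limma-trend adjusted p = 2.1e-09). The largest falls were those of GXM22_RS13780 (131 ± 18.5 against 5033 ± 820.4, log2 fold change -5.25, SE 0.16, limma-trend adjusted p = 5.6e-10) and of the permease gene GXM22_RS09880 (3.96 ± 0.271 against 90.04 ± 51.9, log2 fold change -4.07, SE 0.34, limma-trend adjusted p = 2.5e-06). FeoB (GXM22_RS11200) stood at 69.6 ± 13.1 against 946 ± 423 (log2 fold change -3.68, SE 0.27, limma-trend adjusted p = 8.6e-07).

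In the translation lists 39 of 56 ribosomal protein genes fell and 2 rose on NAG (2 higher and 41 lower adjusted over the list alone; camera adjusted p = 6.4e-13, and adjusted p = 0.4 with an estimated correlation). Also, 13 of 21 tRNA ligase genes fell (0 higher and 15 lower adjusted over the list alone; camera adjusted p = 1.2e-04, and adjusted p = 0.4 with an estimated correlation). The largest fall of each was L24 (GXM22_RS13410, log2 fold change -1.10) and tyrosine-tRNA ligase (GXM22_RS07535, -1.17). Phage and mobile element genes rose, 28 of 102 with 0 lower (27 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0024, and adjusted p = 0.4 with an estimated correlation). In glycolysis 0 of 15 rose and 8 fell (0 and 8 adjusted over the list alone; camera adjusted p = 0.005, and adjusted p = 0.4 with an estimated correlation), phosphoglycerate kinase (GXM22_RS10830, 10144 against 19809, -0.97) among the falls. The amino acid synthesis list was lower (3 of 49 rose and 16 fell, 3 and 16 adjusted over the list alone; camera adjusted p = 0.0035, and adjusted p = 0.4 with an estimated correlation). So was the phosphate and peptide transport list (1 of 17 rose and 7 fell, 1 and 7 adjusted over the list alone; camera adjusted p = 0.039, and adjusted p = 0.4 with an estimated correlation), lost without NAG replicate 1 (camera adjusted p = 0.055) and with edgeR RLE factors (adjusted p just over 0.05). Among sugar-type regulators 3 of 21 rose and 9 fell (3 and 10 adjusted over the list alone). Their list was lower (camera adjusted p = 0.039, and adjusted p = 0.4 with an estimated correlation). That call was lost with no low-value filter (camera adjusted p = 0.074), with edgeR RLE factors (camera adjusted p = 0.16) and with a replicate block. It was also lost without NAG replicate 2, fructose replicate 1, fructose replicate 2, glucose replicate 1 or glucose replicate 2.

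The butyrate fermentation list did not pass as a whole on NAG (camera adjusted p = 0.075, and adjusted p = 0.57 with an estimated correlation), yet single genes in it fell. Acetyl-CoA acetyltransferase (GXM22_RS07055) stood at 6913 ± 1312 against 24475 ± 2459 (log2 fold change -1.83, SE 0.16, limma-trend adjusted p = 3.0e-06). Enoyl-CoA hydratase (GXM22_RS07060) stood at 3563 ± 669 against 12384 ± 1049 (log2 fold change -1.81, SE 0.16, limma-trend adjusted p = 4.1e-06). 3-hydroxybutyryl-CoA dehydrogenase (GXM22_RS07065) stood at 8412 ± 714 against 27662 ± 1761 (log2 fold change -1.72, SE 0.14, limma-trend adjusted p = 2.4e-06). In that list 3 of 20 rose and 7 fell (3 and 7 adjusted over the list alone). Among sugar ABC transporters 7 of 27 rose and 10 fell (7 and 10 adjusted over the list alone), and among glycoside hydrolases and glycogen genes 5 of 21 rose and 7 fell (6 and 8 adjusted over the list alone). An alpha-glucosidase gene (GXM22_RS08095) rose to 2739.9 ± 671 from 692 ± 108 (log2 fold change 1.97, SE 0.17, limma-trend adjusted p = 2.9e-06). Trigger factor (GXM22_RS02965), a ribosome-bound chaperone, stood at 2121 ± 85.3 against 615 ± 77.2 (log2 fold change 1.79, SE 0.15, limma-trend adjusted p = 2.2e-06). The chaperone HtpG (GXM22_RS09940) stood at 238 ± 43.3 against 675 ± 23.3 (log2 fold change -1.51, SE 0.15, limma-trend adjusted p = 8.3e-06). In their list 6 of 24 rose and 7 fell (6 and 8 adjusted over the list alone).

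Rises and falls in the lists not yet named, whose camera calls did not pass between NAG and glucose, were 8 and 0 of 16 ATP synthase genes, 8 and 7 of 27 in nucleotide synthesis, 1 and 3 of 9 in pentose use, 3 and 0 of 8 redox genes and 4 and 2 of 19 in cell wall synthesis. They were 6 and 2 of 33 in cell division and replication, 8 and 0 of 27 of sporulation type, 9 and 13 of 56 in the B vitamin list and 3 and 6 of 20 iron and metal genes. In all, 982 of 2727 genes passed, 503 higher and 479 lower on NAG, 288 and 127 by at least 2-fold. Here the authors' deposited table has 791 genes (390 higher and 401 lower). Total-count scaling moved the median gene by 0.19 and the higher share of calls from 51.2% to 68.7%, and upper quartile factors moved them by -0.07 and to 42.9%, with no call reversed. NAG and glucose cultures also differed in harvest density (OD600 0.2 and 0.4), so the same limit holds.

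Between fructose and NAG, both harvested at OD600 0.2, the same run of 3 genes had the largest rises under the naming rule. GXM22_RS09795 stood at 539.9 ± 16.7 on fructose and 21.6 ± 3.18 on NAG (log2 fold change 4.59, SE 0.25, limma-trend adjusted p = 1.7e-07). GXM22_RS09805 stood at 2687 ± 167 and 111 ± 4.95 (log2 fold change 4.58, SE 0.16, limma-trend adjusted p = 3.2e-09), and GXM22_RS09800 at 686 ± 42.3 and 31.2 ± 10.9 (log2 fold change 4.46, SE 0.23, limma-trend adjusted p = 1.2e-07). In the PTS list 1 of 19 rose and 1 fell (1 and 1 adjusted over the list alone). Enzyme I (GXM22_RS01250) was at 2597 ± 263 and 2966 ± 252 (limma-trend adjusted p = 0.28). The fall, that of GXM22_RS00590 (-0.49), was lost without NAG replicate 1 (limma-trend adjusted p = 0.074) and in a fit of only the 4 libraries compared (adjusted p = 0.057). In the amino sugar list 1 of 8 rose and 3 fell (2 and 3 adjusted over the list alone). N-acetylneuraminate lyase (GXM22_RS08055) was lower on fructose (-1.13), a call lost without NAG replicate 1 (limma-trend adjusted p = 0.081), NAG replicate 2 (0.063) and fructose replicate 1 (0.058). In the fructose use list 1 of 6 rose and 1 fell (1 and 2 adjusted over the list alone), and in the galactose use list 2 of 8 rose and 0 fell (2 and 0 adjusted over the list alone).

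Among the deepest falls on fructose against NAG were transport and uncharacterised genes. The MATE family efflux gene GXM22_RS09410 stood at 142 ± 11.2 against 788 ± 69 (log2 fold change -2.46, SE 0.14, limma-trend adjusted p = 2.3e-07). Uncharacterised GXM22_RS00490 stood at 35.8 ± 19.3 against 167 ± 32.4 (log2 fold change -2.28, SE 0.36, limma-trend adjusted p = 9.6e-04). A run of neighbouring numbers followed, with the S-layer domain gene GXM22_RS04550 (309 ± 19.2 against 1379.8 ± 87.9, log2 fold change -2.15, SE 0.20, limma-trend adjusted p = 3.1e-05). In it were also the HlyD-type adaptor gene GXM22_RS04535, the FtsX-like permease gene GXM22_RS04545 and the ABC ATPase gene GXM22_RS04540 (log2 fold changes -2.09, -2.03 and -1.95). Sugar-type regulators were higher on fructose (8 of 21 rose and 1 fell, 10 and 1 adjusted over the list alone; camera adjusted p = 0.0048, and adjusted p = 0.44 with an estimated correlation). Chaperones were higher too (13 of 24 rose and 7 fell, 13 and 7 adjusted over the list alone). Their camera adjusted p was 0.022, and 0.74 with an estimated correlation. That call was lost without fructose replicate 2, and the list did not pass by fry (adjusted p = 0.095). It passed by the mixed fry test (adjusted p = 1.5e-04). GroES (GXM22_RS06680) stood at 449 ± 65.4 against 109 ± 19.1 (log2 fold change 2.04, SE 0.18, limma-trend adjusted p = 1.7e-05) and GroEL (GXM22_RS06685) had a log2 fold change of 1.66. ATP synthase genes were higher (6 of 16 rose and 0 fell, 8 and 0 adjusted over the list alone; camera adjusted p = 6.3e-04, and adjusted p = 0.44 with an estimated correlation). The F0 subunit C gene GXM22_RS04305 led (1.13), a call lost without NAG replicate 2 (limma-trend adjusted p = 0.068). Ribosomal proteins were lower (0 of 56 rose and 7 fell, 0 and 7 adjusted over the list alone). Their camera adjusted p was 1.0e-04, and 0.74 with an estimated correlation, and they did not pass by fry (adjusted p = 0.15). Cell wall synthesis was lower as well (1 of 19 rose and 6 fell, 1 and 8 adjusted over the list alone). Its camera adjusted p was 0.025, and 0.74 with an estimated correlation. That call was lost without NAG replicate 1 or fructose replicate 2, and the list did not pass by fry (adjusted p = 0.058). The mixed fry test did call it (adjusted p = 7.5e-04).

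Sugar ABC transporter genes GXM22_RS12610, GXM22_RS14690 and GXM22_RS14685 were higher on fructose than on NAG (log2 fold changes 2.41, 2.15 and 2.08). So was GXM22_RS14675 (1644 ± 199 against 629 ± 57.9, log2 fold change 1.38, SE 0.13, limma-trend adjusted p = 3.1e-05), of glycoside hydrolase family 32, which holds fructan- and sucrose-cleaving enzymes. In the sugar ABC transporter list 4 of 27 rose and 5 fell (4 and 5 adjusted over the list alone), and in the glycoside hydrolase and glycogen list 2 of 21 rose and 3 fell (3 and 3 adjusted over the list alone). Other rises and falls were 1 and 1 of 15 in glycolysis, 6 and 2 of 20 in butyrate fermentation and 3 and 1 of 9 in pentose use. Next were 0 and 4 of 21 tRNA ligases, 6 and 3 of 49 in amino acid synthesis and 0 and 3 of 27 in nucleotide synthesis. They were 1 and 2 of 8 redox genes, 0 and 9 of 33 in cell division, 1 and 3 of 27 of sporulation type, 6 and 1 of 102 phage genes, 5 and 8 of 56 in the B vitamin list, 2 and 1 of 20 iron genes and 1 and 0 of 17 in phosphate and peptide transport. In all, 580 of 2727 genes passed, 251 higher and 329 lower on fructose, 95 and 64 by at least 2-fold. Against this the authors' deposited table has 488 genes (196 higher and 292 lower). The count was 385 without NAG replicate 1 and 367 without NAG replicate 2. Upper quartile factors moved the median by 0.12 and the higher share from 43.3% to 61.5% (58.1% with total-count scaling).

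Some of the genes that had risen on galactose over glucose also stood far lower on fructose and NAG than on galactose. GXM22_RS09880 stood at 1683 ± 278 on galactose against 6.43 ± 0.8 on fructose (log2 fold change -7.82, SE 0.34, limma-trend adjusted p = 4.0e-09) and 3.96 ± 0.271 on NAG (log2 fold change -8.40, SE 0.34, limma-trend adjusted p = 1.6e-09). Cysteine synthase A (GXM22_RS02915) had log2 fold changes of -6.24 on fructose and -6.40 on NAG, and galactokinase (GXM22_RS09950) of -3.76 and -3.87. The EIIC gene GXM22_RS00590 stood at 24676 ± 394 on galactose, against 1651 ± 70.4 on fructose (log2 fold change -3.90, SE 0.12, limma-trend adjusted p = 1.1e-10) and 2323 ± 197 on NAG (log2 fold change -3.41, SE 0.12, limma-trend adjusted p = 3.0e-10). Enzyme I (GXM22_RS01250) was higher on both, by 2.07 on fructose and 2.26 on NAG, and HPr (GXM22_RS01245) by 1.90 and 2.0. GXM22_RS09805 rose on fructose (log2 fold change 4.07, SE 0.16, limma-trend adjusted p = 1.5e-09). On NAG it fell (log2 fold change -0.51), a call lost without NAG replicate 1 (limma-trend adjusted p = 0.061), NAG replicate 2 (0.12), galactose replicate 1 (0.22) and with total-count scaling (adjusted p = 0.2). In the PTS list 4 of 19 rose and 3 fell (4 and 3 adjusted over the list alone) on fructose and 3 of 19 rose and 5 fell (3 and 6 adjusted over the list alone) on NAG. In the amino sugar list 0 of 8 rose and 2 fell (0 and 2 adjusted over the list alone) on fructose, and 3 of 8 rose and 1 fell (3 and 1 adjusted over the list alone) on NAG. N-acetylneuraminate lyase (GXM22_RS08055) rose on NAG (log2 fold change 1.87, SE 0.29, limma-trend adjusted p = 2.4e-04).

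On fructose against galactose the list calls were lower galactose use (0 and 3 of 8 rose and fell; camera adjusted p = 0.0092, and adjusted p = 0.26 with an estimated correlation) and the translation lists. These were ribosomal proteins (2 and 50 of 56; camera adjusted p = 8.5e-16, and adjusted p = 0.66 with an estimated correlation) and tRNA ligases (0 and 15 of 21; camera adjusted p = 6.1e-06, and adjusted p = 0.66 with an estimated correlation). Higher were ATP synthase (14 and 0 of 16; camera adjusted p = 2.6e-06, and adjusted p = 0.26 with an estimated correlation) and phage genes (37 and 1 of 102; camera adjusted p = 1.3e-04, and adjusted p = 0.26 with an estimated correlation). Glycolysis was lower (2 and 8 of 15; camera adjusted p = 0.036, and adjusted p = 0.66 with an estimated correlation), a call lost without fructose replicate 2 (camera adjusted p = 0.17), without galactose replicate 2 (camera adjusted p = 0.069) and with total-count scaling (adjusted p = 0.064). Lower butyrate fermentation (3 and 8 of 20; camera adjusted p = 0.036, and adjusted p = 0.66 with an estimated correlation) had a median of -0.18 that turned to 0.14 under total-count scaling. Its list call was lost without fructose replicate 2 (camera adjusted p = 0.072), without galactose replicate 2 (camera adjusted p = 0.12), with total-count scaling (adjusted p = 0.097) and with edgeR RLE factors (adjusted p = 0.058). Lower amino acid synthesis (1 and 15 of 49; camera adjusted p = 0.022, and adjusted p = 0.66 with an estimated correlation) had a median of -0.26 that turned to 0.06 under the same scaling. That call was lost with total-count scaling (adjusted p = 0.066). The lower B vitamin list (3 and 13 of 56; camera adjusted p = 0.036, and adjusted p = 0.66 with an estimated correlation) had a median of -0.32 that turned to 0.01 there. The B vitamin call was lost without fructose replicate 1 (camera adjusted p = 0.13), without galactose replicate 2 (camera adjusted p = 0.12), with total-count scaling (adjusted p = 0.064) and with edgeR RLE factors (adjusted p = 0.089).

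On NAG against galactose the lower lists were galactose use (0 and 5 of 8; camera adjusted p = 5.3e-04, and adjusted p = 0.32 with an estimated correlation) and glycolysis (0 and 9 of 15; camera adjusted p = 0.0097, and adjusted p = 0.49 with an estimated correlation). Ribosomal proteins (3 and 39 of 56; camera adjusted p = 2.1e-10, and adjusted p = 0.49 with an estimated correlation) and tRNA ligases (0 and 12 of 21; camera adjusted p = 7.3e-04, and adjusted p = 0.49 with an estimated correlation) were lower too. So was amino acid synthesis (3 and 18 of 49; camera adjusted p = 7.3e-04, and adjusted p = 0.49 with an estimated correlation). Phosphate and peptide transport was lower (1 and 7 of 17; camera adjusted p = 0.048, and adjusted p = 0.45 with an estimated correlation), lost without NAG replicate 1 (camera adjusted p = 0.063) and without galactose replicate 2 (camera adjusted p = 0.084). ATP synthase was higher (8 and 1 of 16; camera adjusted p = 0.0076, and adjusted p = 0.45 with an estimated correlation), lost without NAG replicate 1 (camera adjusted p = 0.063). Phage genes were higher (27 and 5 of 102; camera adjusted p = 0.0076, and adjusted p = 0.45 with an estimated correlation), lost with total-count scaling (adjusted p = 0.074). Fructose against galactose had 1146 genes past the test (546 higher and 600 lower) and NAG against galactose 994 (497 and 497). For these pairs the authors' deposited tables have 983 genes (447 higher and 536 lower) and 845 genes (415 higher and 430 lower). Total-count scaling moved their medians by 0.32 and 0.22 and their higher shares of calls from 47.6% and 50% to 74.3% and 68.3%. Upper quartile factors moved the medians by 0.02 and -0.10 and the shares to 49.3% and 40.2%. Both pairs differ in harvest density as well as sugar, with the same limit.

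Some genes stood apart on one sugar, past the test and at least 2-fold in the same direction against each of the other 3. Fructose had 62 such genes, NAG 35, galactose 15 and glucose 6. On fructose 41 were higher. Among genes of at least 10 CPM, ordered here and below by the smallest of the 3 fold changes, they were led by the near-floor gene GXM22_RS03695 (43.3 ± 21.7 against 1.78 ± 0.249, 1.71 ± 0.477 and 2.51 ± 3.55), uncharacterised GXM22_RS14825 (7616, against at most 541) and GXM22_RS09805. The other 21 were lower, led by the ABC ATPase gene GXM22_RS11185 (11.5, against at least 44.8). On NAG 20 were higher, led by GXM22_RS00490 and GXM22_RS09410, and 15 lower, led by GXM22_RS13780 and HtpG (GXM22_RS09940, 238 against 719, 675 and 658). On galactose 12 were higher, among them GXM22_RS09875, GXM22_RS02915, GXM22_RS09880 and GXM22_RS13780, and 3 lower, the fructose-bisphosphatase GXM22_RS09290, HPr GXM22_RS01245 and enzyme I GXM22_RS01250. The 6 genes of glucose were lower there, led by GXM22_RS00900 (2.73 against 20.4, 24.2 and 303). The glucose count was 1 without galactose replicate 2 and 18 without glucose replicate 2, 3 with edgeR, DESeq2 or total-count scaling and 2 with a pseudocount of 5, and the NAG count 23 without fructose replicate 2. With a replicate block the galactose count was 23 and the glucose count 23.

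Across the split of fructose and NAG from glucose and galactose, 536 genes passed all 4 tests in the same direction, 255 higher and 281 lower on fructose and NAG. The other ways to pair the sugars gave 2 and 2. Both include the test between galactose and glucose, where only 42 genes passed, so neither could have exceeded that count. The higher genes include the metallo-hydrolase GXM22_RS00435 (2356 and 2480.3 on fructose and NAG against 96.9 and 65.5 on glucose and galactose), sugar ABC permeases GXM22_RS00440 and GXM22_RS00445, 8 of 16 ATP synthase genes and 19 of 102 phage genes. The lower genes include FeoB (GXM22_RS11200, 45 and 69.6 against 946 and 2138), GXM22_RS13780, the EIIC gene GXM22_RS00590, 39 of 56 ribosomal protein genes, 11 of 21 tRNA ligase genes, 7 of 15 glycolysis genes and 3 of 8 galactose use genes. Of 20 simulations with no effect, the highest count was 0. With a mean of 0.433 calls per comparison in them, a gene past all 4 tests was hardly possible. They held no effect of density either, so they do not bear on the cause of the split. The split follows harvest density (OD600 0.2 against 0.4), so sugar and density cannot be told apart.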

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

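Total-count scaling and edgeR with TMM factors were chosen after seeing the data; the other alternatives were planned. For the named genes, 10108 results under an alternative stayed on the same side of the threshold, 424 fell below it and 79 rose past it. Where either fit passed, 0 changed direction. A gene that passed in neither fit counts as having stayed, whatever its direction. For the lists called by camera 514 stayed and 88 fell below it.

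The 42 genes of galactose minus glucose became 98 with a replicate block, 25 at an adjusted p under 0.01 and 23 with a 2-fold limit. Genes specific to galactose (15) became 23 with the block. Genes specific to glucose (6) numbered 3 with edgeR and TMM, RLE or upper quartile factors, with DESeq2, with total-count scaling and at an adjusted p under 0.01, then 2 with a pseudocount of 5 and 23 with the block. With the block the other comparisons rose as well, to 1271 genes in fructose minus glucose, 1060 in NAG minus glucose, 1227 in fructose minus galactose, 1080 in NAG minus galactose and 706 in fructose minus NAG. Libraries with the same replicate number correlated weakly across sugars (0.01 to 0.18 after removing sugar means), and whether the numbers pair them stays open. With the block, the named genes stayed in 584 cases, 8 rose past the threshold and 0 fell below it, while the regulator list in NAG minus glucose (camera) fell below it at an adjusted p of 0.066; its other alternatives are given in the report.

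An adjusted p under 0.01 left 653 genes in NAG minus glucose, 298 in fructose minus NAG and 354 separating genes, by construction fewer. A 2-fold limit left 482 in fructose minus glucose, 415 in NAG minus glucose, 508 in fructose minus galactose, 419 in NAG minus galactose, 159 in fructose minus NAG and 163 separating genes. Lists called by camera numbered 8 in fructose minus glucose, 9 in NAG minus glucose, 4 in galactose minus glucose, 9 in fructose minus galactose, 8 in NAG minus galactose and 5 in fructose minus NAG. An estimated correlation made each of them 0, and fry gave 14, 17, 1, 15, 17 and 5. Total-count scaling made the 9 lists of fructose minus galactose 5. For the counts that changed by other than a stricter limit, the cause was not tested.

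Leaving out each library in turn, the counts ranged over 882 to 1166 in fructose minus glucose, 693 to 1060 in NAG minus glucose, 20 to 65 in galactose minus glucose, 849 to 1136 in fructose minus galactose, 694 to 1068 in NAG minus galactose and 367 to 596 in fructose minus NAG. Galactose minus glucose fell to 20 without galactose replicate 1 or galactose replicate 2 and to 25 without glucose replicate 1, and rose to 65 without fructose replicate 2. Fructose minus NAG fell to 385 without NAG replicate 1 and 367 without NAG replicate 2. Separating genes ranged over 415 to 562. Genes specific to galactose ranged over 12 to 19, to glucose 1 (without galactose replicate 2) to 18 (without glucose replicate 2), to fructose 54 to 88 and to NAG 23 (without fructose replicate 2) to 45. Lists called ranged over 6 to 8, 8 to 9, 3 to 5, 6 to 9, 7 to 8 and 5 to 6 in the order above. These fits pool the spread, so a lone library is assumed to vary like the other groups. Removing stable RNA genes was not run, as the tables hold none, and depth limits low genes, at a floor of 3 reads worth 0.954 to 2.25 CPM.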

Other observations

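The tests of a wider rise of sulfur amino acid genes, of the share over all genes for density and of density for the EIIC gene, as well as total-count scaling and edgeR with TMM factors, were chosen only after the results were seen. Lists that camera did not call held marked changes in single genes, and a gene given below went against a list that it called. In pyrimidine synthesis orotate phosphoribosyltransferase (GXM22_RS02815) stood at 779.9 ± 207 on fructose and 843 ± 27.5 on NAG against 1566 ± 60.6 on glucose, with log2 fold changes of -1.03 (SE 0.16, limma-trend adjusted p = 2.4e-04) and -0.89 (SE 0.16, limma-trend adjusted p = 8.3e-04). Its neighbour GXM22_RS02820, for the small subunit of carbamoyl-phosphate synthase, had -0.93 on fructose and -0.86 on NAG. Thioredoxin (GXM22_RS02155), a disulfide reductant, rose to 605 ± 70.9 on fructose (log2 fold change 1.84, SE 0.14, limma-trend adjusted p = 9.6e-07) and 537 ± 18.2 on NAG (log2 fold change 1.68, SE 0.14, limma-trend adjusted p = 3.0e-06) from 168 ± 17.9 on glucose. A rubrerythrin family gene (GXM22_RS12900), of a group of peroxide-reducing proteins, rose on NAG to 1146 ± 136 from 537 ± 81.1 (log2 fold change 1.10, SE 0.16, limma-trend adjusted p = 1.9e-04). The rise of GXM22_RS12900 on fructose (log2 fold change 0.51, SE 0.16, limma-trend adjusted p = 0.02) was lost without fructose replicate 1 (limma-trend adjusted p = 0.12) and glucose replicate 2 (0.18).

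In cell shape and replication, MreD (GXM22_RS05435) and MreC (GXM22_RS05430), which help to place cell wall synthesis, rose on NAG over glucose with log2 fold changes of 1.01 and 0.85. Alanine racemase (GXM22_RS01625), which makes D-alanine for the wall, stood at 292 ± 68.3 on fructose against 564 ± 15.9 on glucose (log2 fold change -0.97, SE 0.16, limma-trend adjusted p = 3.3e-04). The replication initiator DnaA (GXM22_RS00005) stood at 909.5 ± 21.2 on fructose against 1656 ± 69.1 on NAG (log2 fold change -0.86, SE 0.12, limma-trend adjusted p = 3.3e-04). Of sporulation-type genes, stage II sporulation protein P (GXM22_RS02090) rose on NAG to 54.6 ± 2.79 from 19.3 ± 5.61 (log2 fold change 1.48, SE 0.32, limma-trend adjusted p = 0.003) and a SpoIIE family phosphatase gene (GXM22_RS13835) on fructose (log2 fold change 0.91, SE 0.22, limma-trend adjusted p = 0.0047). The phosphate-binding gene GXM22_RS09855 rose on NAG (log2 fold change 1.04, SE 0.18, limma-trend adjusted p = 7.4e-04), and the amino acid permease gene GXM22_RS11880 stood at 213 on fructose against 494 (log2 fold change -1.24, SE 0.18, limma-trend adjusted p = 1.2e-04). The phosphate and peptide transport list was called lower in NAG minus glucose (camera adjusted p = 0.039), with 1 rise among 17 genes.

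A run of dTDP-rhamnose genes, chosen after their values were seen, was higher on fructose and NAG. GXM22_RS02995, for glucose-1-phosphate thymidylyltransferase, stood at 1147 on galactose and 1108 on glucose against 5658 on fructose and 7988 on NAG (log2 fold changes over glucose 2.35 and 2.85). GXM22_RS03000, for dTDP-4-dehydrorhamnose reductase, had 2.16 and 2.69, and GXM22_RS03005, for dTDP-glucose 4,6-dehydratase, 2.31 and 2.77. dTDP-rhamnose is a precursor of surface polysaccharides.

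The first pattern weighed is the 536 genes that separate fructose and NAG from glucose and galactose. Under 4 other scalings, at least 76.7% of them passed all 4 tests in the same direction. The lowest share was with total-count scaling, then 95.5% with upper quartile, 97.9% with TMM and 98.3% with RLE factors. RLE factors hardly differed from the authors' size factors (median gene moved by 0.0045 in fructose minus glucose), so their share tests little. With every library thinned to 1332716 reads 90.1% passed. Neither the authors' normalization nor library depth thus accounts for most of these genes. Of these genes 19.96% passed the test between fructose and NAG, which were harvested at the same density, but so did 21.3% of all genes tested, and a gene can differ between this pair and still owe its separation to density, so the planned limit of 10% does not speak against density as the only cause. With 0 sugars harvested at both densities, sugar and density cannot be told apart for these genes, whether or not they differ between fructose and NAG.

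The second pattern is the lower level on NAG of the EIIC gene GXM22_RS00590, beside the genes for using glucosamine 6-phosphate, which is at 2323 ± 197 on NAG, 15336 ± 317 on glucose and lower still on fructose, at 1651 ± 70.4. Its log2 fold change over glucose of -2.72 came no nearer to 0 than -2.53 under the 4 other scalings. These moved the median gene of this comparison by at most 0.19 (total-count scaling), so the test could hardly fail. A shift of that size does not account for the fall. It did not move as 1 unit with GXM22_RS00595 and GXM22_RS00600, whose log2 fold changes were 0.16 and, the higher, 0.21. For reads shared with GXM22_RS14870, the other gene with the product name EIIC, the planned test could not decide. The log2 fold change of GXM22_RS14870, -0.90 (SE 0.25), lay neither below -1 nor above it by more than 2 SE. That call was lost without NAG replicate 1, NAG replicate 2 or glucose replicate 1. Yet GXM22_RS14870 stood at only 65.2 ± 0.196 on NAG and 122 ± 1.1 on glucose. These levels argue against such reads as the source of the fall of GXM22_RS00590 from 15336 to 2323. Reads shared with other PTS genes were not tested. With 0 sugars harvested at both densities, sugar and density cannot be told apart for GXM22_RS00590.

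The third pattern is the rise on galactose over glucose of GXM22_RS02915, GXM22_RS13780, GXM22_RS09875 and GXM22_RS09880. Of these 4 genes, 0 lost the limma-trend call without any 1 of the 4 libraries, which argues against a single library. Under the 4 other scalings 0 lost it. Those scalings moved the median gene by -0.037 (total-count) to 0.024 (upper quartile), beside fold changes of 1.82 to 4.56. The calls could thus hardly be lost, and shifts of that size do not account for the rises. Of 33 other genes matched by sulfur words, 0 were called by limma-trend, edgeR or DESeq2, and 1 had an unadjusted p under 0.05. Their median log2 fold change was -0.016 (quartiles -0.11 and 0.18). That word list holds many genes outside sulfur amino acid synthesis, such as tRNA ligases, desulfurases, iron-sulfur enzymes and a cysteine protease. Its median therefore cannot decide whether that synthesis rose more widely. The methionine synthesis genes in it were among those not called. No biological explanation was tested.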
